A study of Mus musculus with 1000 samples.

How the data were processed

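The series describes 3' RNA sequencing of brain from mice descended from ENU-mutagenized males. ENU is a chemical mutagen that causes mostly single base changes. Per the labels' protocols, founder males were of the C57BL/6NCrl strain, and the brain was collected from mice of the third generation after removal of the cerebellum. Total RNA was converted to cDNA by 3' priming, cDNAs of one row of a multi-well plate were pooled after each had received its own in-line index, and the pools were then combined for sequencing. The submitters' processing notes name the aligner GSNAP and the genome build GRCm38; no version is given in the sources used here.

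No expression value was analysed here. The table used here was deposited by the authors as an index: it has 3 columns, which hold a row number, a library name and the name of 1 of 3 parts of the processed data. It was tested for columns of expression values and has 0. Sequencing depth per sample was therefore not examined, and no normalization, filter on low counts, fold change or gene-level test was applied. The 2 gene comparisons planned before the data were examined, and the 12 gene lists fixed for them, were not run; the rule for named genes therefore named none.

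The table lists 23231 libraries. All 1000 samples of the series matched 1 library name each, by identity with the title. The other 22231 names belong to samples not analysed here and were counted but not used. Samples were grouped by the labels for candidate gene or pedigree and for genotype; mice that the labels place outside the annotated subset formed their own group. The plate label and well were read from the titles, as was the number after the letter S, called the pool label here although no label defines it, and the letters ENU and the digits after them at the start of each title were taken as the title prefix. The labels do not say that a prefix is a pedigree.

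The 2 protein changes named in the labels were placed on the GENCODE vM21 transcripts of GRCm38, the build that the processing notes name. Codons were counted from the first coding base of each annotated transcript, and every single base change of the reference codon was translated to see which gives the labelled residue. Genomic coordinates are 1-based. The variants themselves were not called here. Genotype counts were tested with an exact multinomial test. Python 3.11.15 and pandas 2.3.3 were used.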

Results

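The 1000 samples were brain RNA libraries from mice of an ENU mutagenesis screen, in which RNA profiles were searched for abnormal inflammation states and exome sequencing was used to find the candidate mutations. The labels annotated 35 mice in more detail, and the remaining mice carried no genotype or phenotype label. Of the 35, the label for candidate gene or pedigree was Pigv N30S in 12 mice, Nlrp1a D573G in 12 and Unaffected in 11. This label does not say that each mouse carried the change, and 1 of the 12 Nlrp1a mice had the genotype label +/+. Expression values and sequencing depths were not analysed here, so no difference in gene expression between these groups is reported.

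Nlrp1a encodes an inflammasome sensor of the innate immune system. All 12 mice labelled Nlrp1a D573G had a genotype label. Of these, 2 were m/m, 9 were m/+ and 1 was +/+. The phenotype label, reactive astrocytes, was given to the 2 m/m mice and to none of the other 10. A missing label does not show that the phenotype was absent, and the labels do not say whether the other 10 mice were scored, so no test was made. The labels name Nlrp1a as the candidate gene or pedigree of these same mice, so this count cannot be taken as independent evidence for it. The labels do not say what the phenotype label rests on.

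Pigv encodes a mannosyltransferase of glycosylphosphatidylinositol anchor synthesis. Among the 12 mice labelled Pigv N30S, 3 had the genotype label m/m, and the same 3 carried the phenotype label "High MG signature". The other 9 mice had neither a genotype nor a phenotype label. Genotype and phenotype could therefore not be cross-tabulated, and no test was made. The labels also name Pigv as the candidate gene or pedigree of these same mice. The overlap of the 2 labels in 3 mice is therefore not independent evidence for Pigv. None of the 11 mice labelled unaffected had a genotype label. A histology block label was given for 5 mice, which were the 5 with a phenotype label.

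Both labelled changes were located in the reference annotation. Nlrp1a (ENSMUSG00000069830.10) lies on the minus strand of chromosome 11, from 71092236 to 71144704 in GRCm38. The labelled residue was aspartate in both of its annotated coding transcripts, with the codon GAC at 71122704 to 71122706. This codon is in exon 2 of 14 in transcript Nlrp1a-201 and in exon 3 of 14 in Nlrp1a-202. A single base change of that codon gives glycine, A1718G, counted from the first coding base on the coding strand, at genomic position 71122705.

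Pigv (ENSMUSG00000043257.15) lies on the minus strand of chromosome 4, from 133660387 to 133672647. In transcript Pigv-201, residue 30 is asparagine, with the codon AAC at 133665768 to 133665770 in exon 3 of 4. A single base change of that codon gives serine, A89G on the coding strand, at genomic position 133665769. In the shorter coding transcript, Pigv-202, residue 30 is arginine and lies in a different place, at 133662780 to 133662782, so the label matches Pigv-201 and not Pigv-202. For both genes the base change that gives the labelled residue is an A-to-G change on the coding strand at position 2 of the codon.

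The libraries came from 20 plate labels and 85 plate rows, and no plate and well position was used more than once. The titles held 88 prefixes, of which 78 had 12 mice, 1 had 10 and 9 had 6. Each of the 88 prefixes fell within 1 plate row. In 82 of the 85 rows all libraries shared 1 prefix, and the other 3 rows held 2 prefixes. The Nlrp1a mice occupied row B of plate label neuro2092, the Pigv mice row D of neuro2088, and the unaffected mice row A of neuro2089. The last of these rows held 12 mice of 1 prefix, of which 11 were labelled unaffected. The titles held 71 pool labels for the 85 rows. Of these labels, 14 occurred in 2 rows, so the pool label alone did not identify a row. No label says whether a repeated pool label stands for the same pool, and the protocols describe pooling within 1 row. Mice of the 3 Nlrp1a genotypes shared 1 plate row and 1 pool label, whereas a comparison between the 3 annotated sets of mice could not be told apart from a comparison between rows. Another 6 titles contained the gene symbol Ms4a7, without a genotype label. Titles with other gene symbols were not counted. Ms4a7 is not named by any label for candidate gene or pedigree, and what the symbol marks in these titles was not examined.

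All 1000 libraries were assigned by the deposited index to 1 of its 3 parts, part 2, which lists 7743 libraries.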

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

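The layout counts did not change with the source of the layout: reading the plate label and well from the index in place of the titles gave 1000 samples and 88 prefixes within 1 plate row, as did counting only samples found in the index. The index names are identical to the titles, so neither choice could have moved these counts. Other normalizations, low-value filters, pseudocounts and left-out replicates, chosen before the data were examined, were not run, because no expression values were analysed here. No paired analysis was run, for the same reason and because the replicate numbers only name samples.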

Other observations

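The test in this part was chosen after the genotype labels were seen. The 12 Nlrp1a mice comprised 2 m/m, 9 m/+ and 1 +/+, against 3, 6 and 3 for offspring of 2 heterozygous parents. The counts did not depart detectably from that ratio (exact multinomial test against 1:2:1, p = 0.239). With 12 mice such a test can detect only large departures, and no other ratio was tested, so the result does not establish such a cross. The test also treats the 12 mice as unselected, but they were annotated as a candidate set. The labels do not say how they were chosen, and a choice that depended on m/m mice would alter the p-value. The presence of both homozygous classes excludes any other single pair of parents, but the parents are not labelled and several litters from different parents remain possible.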
